A study of Rattus norvegicus with 3 samples.

How the data were processed

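Gene expression was measured on 3 one-colour Agilent rat arrays, each hybridised with Cy3-labelled cRNA made from the total RNA of ROS17/2.8 cells. One array came from cells given 1 mg/ml polyphosphate (the high dose), another from cells given 0.01 mg/ml (the low dose), and the remaining array from cells without polyphosphate (the control), with a treatment time of 24 h per the labels for the treated cells and none given for the control. The groups were taken from the treatment labels. Each group holds 1 array, so there is no biological replicate, no SD between samples and no p-value anywhere in the text. All 3 arrays lay on the same slide, and the position on the slide cannot be told apart from the group.

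The spot intensity values were deposited by the authors as scanner output. Per the file headers they were extracted with Agilent Feature Extraction 10.7.3.1 under the protocol GE1_107_Sep09 for array design 028279, whose probe coordinates refer to the rat build rn4. The processed signal is an intensity on a linear scale that, per the file headers, had been background-subtracted and detrended within the array, with surrogate values for spots at background, and it was not normalized between arrays. The same deposited files give 0 or 1 flags for spots well above background, saturated spots and outlier spots. The authors also deposited a series table whose processing is not given in the sources used here. The values that the authors deposited there are a ratio: checked against the scanner values, each column was the processed signal over 1 constant per array, with a deviation of at most 0.0002% within an array. The constants were 823 for the high dose, 849 for the low dose and 823 for the control, close to the 75th percentile of all spots, and the column medians were 0.0734, 0.0731 and 0.0737. The table is thus uncentred between genes and on a linear scale, and it served as an alternative that rescales each array as a whole.

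The main value was log2 of the processed signal minus the array's 75th percentile over the 58717 non-control spots. Spots flagged as outliers numbered 352 on the high dose array, 368 on the low dose array and 426 on the control array. They were left out, except that a probe with every spot flagged, such as a flagged single spot, kept its value. No non-control spot was saturated. The remaining spots of a probe were averaged, and a probe counted as well above background where at least 50% of its spots did. Of 30367 probes, 13137 had 1 spot, 15840 had 2 and 1390 had 10. A gene's log2 ratio was the mean over its probes well above background on both arrays compared. Gene symbols were updated through the RefSeq accession of the probe for 18438 probes (60.7%), using a RefSeq gene table of the GRCr8 assembly for names only. The symbol of 2720 probes changed in this way, and the other probes kept the name in the files.

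Each gene was described by a rule of size, at least 2-fold apart. Where a gene was well above background on 1 of the 2 arrays only, a nominal lower bound of the fold was computed from the higher of the dim probe's own level and the lowest level among probes well above background on that array. Where the dim probe's own level was the higher, this is the observed ratio and no true bound. Spots above that lowest level can also miss the flag, so each bound is nominal. For 31 lists fixed in advance (26 gene lists and 5 sets of markers of other cell types), the median log2 ratio was set against the medians of 10000 random lists of the same size, drawn from 20 bins of mean level, and a list needed 5 measured members. A list is called above or below where its median lay outside the central 95% of the random lists. Genes of one pathway are regulated together and random genes are not, so this percentile describes these arrays and is not a p-value. The named genes were the 10 highest and 10 lowest at least 2-fold apart (5 and 5 for high against low) with a gene symbol in the files and all probes in one direction, up to 4 members of each list at least 2-fold apart or otherwise the 2 furthest from 0, the 3 largest bounds in each direction, and always Alpl, Ibsp, Spp1, Bglap, Runx2, Sp7 and Col1a1. Members of a list named beyond this rule were chosen as examples after their values were seen. Not every gene the rule selects is printed. The groups, the main setting, the lists, this rule and the alternatives named first below were fixed before the data were examined.

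The error given as ± is a spot error: the standard error of a log2 ratio from the SD between repeat spots of a probe, pooled in 20 bins of level. It covers the measurement on an array and leaves out labelling, culture and every biological difference. Pooling was first done over probes with at least 50% of their spots well above background, which gave a spot SD of 0.79 in the dimmest bin. After the data were seen it was restricted to probes with all spots well above background, which gave 0.26, because the first version predicted more 2-fold genes from noise alone than were observed. The choice hardly matters for bright spots (SD 0.05 in the brightest bin under either) but decides how dim genes compare with noise. The ± values are from the restricted version, under which dim genes have smaller errors than under the first. Errors under the first version are printed for dim 2-fold genes and some dim list members, with the simulated counts under both for each dose against control over genes measured on all 3 arrays.

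Comparisons against the same control array share its errors, so unchanged arrays were simulated 100 times from the spot error with 1 shared control. The alternatives fixed before were quantile normalization, centring on the median, the 75th percentile of probes well above background on all arrays, normexp background correction (offset 50), no filter on dim probes, genes above the median level only, the brightest probe of a gene, the series table, thresholds of 1.5-fold and 3-fold, and random lists not matched on level. Centring on spike-in probes, probes with repeat spots only, and the restricted version of the spot error were added after the data were seen, and the first version was then kept as an alternative. Centring on the median, on probes well above background or on spike-ins, and the series table, move each array by 1 constant. They leave the percentile of a list as it is, so they could not change its place among random lists. Leaving out replicates was not possible. The procedure was tested on simulated data, arrays of 15056 genes made from the control array and the version of the spot error used, with 200 genes changed. For the simulated high dose against control, all 50 genes changed 3-fold, all 50 changed 4-fold and all 50 changed 8-fold were called at 2-fold, and 1 of 50 changed 1.5-fold. Both simulated arrays kept the background flags of the control array, so no gene could drop below background. This recovery thus says little about genes that fall to the background. Of the 14856 genes outside those 200, 3 were called, a count that rests on the restricted version of the spot error. These 14856 include 25 list genes shifted by 0.30. That list was recovered at 0.33, and 10 of 200 unchanged lists (5.0%) fell outside the central 95%. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.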

Results

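The effect of inorganic polyphosphate on gene expression was measured in ROS17/2.8 cells, a clonal rat osteosarcoma line with osteoblast properties that is used as a model of mineralizing bone cells. Polyphosphate is a linear chain of orthophosphate residues joined by phosphoanhydride bonds. Confluent cells were kept in a medium that promotes mineralization, with ascorbate phosphate and a glycerophosphate, and received a high dose (1 mg/ml) or a low dose (0.01 mg/ml) for 24 h, or no polyphosphate. The labels give no time for the control. There was 1 array per group, so no difference below has a replicate check, and the ± values are spot errors that cover the measurement on an array only. Of 30367 probes, 16982 (55.9%) were well above background on the high dose array, 17195 (56.6%) on the low dose array and 17377 (57.2%) on the control array. The 75th percentile of the signal was 937, 964 and 926 in that order, and 16593 probes were well above background on all 3 arrays. The number of arrays limits the precision of every comparison.

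Spike-in probes gave the shift between arrays. Over 8 of 10 spike-in probes well above background on all arrays, the log2 ratio had an SD of 0.02 for high against control, 0.05 for low against control and 0.03 for high against low. Each of these probes averages 35 spots per array, so this spread is not that of a gene with fewer spots. Over all measured genes the SD was 0.20, 0.16 and 0.19 in that order. The root mean square spot error was 0.146, 0.149 and 0.146, or 0.200, 0.212 and 0.200 under the first version of the spot error. The mean spike-in ratio was -0.15 for high against control, -0.16 for low against control and 0.00 for high against low. Centring on the spike-ins would thus shift every gene up by 0.15 at the high dose and 0.16 at the low dose against control, and the log2 ratios below are given without that shift.

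The first comparison asked how expression differed between cells with the high dose and cells without polyphosphate. Genes of hypoxia and glycolysis were higher on the high dose array as a group, with all 25 measured members above 0 and 20 of them by more than 2 spot errors. The list holds 29 genes, and those without a probe well above background on both arrays, Pfkfb3 among them, have no value here. Their median log2 ratio was 0.28, a fold of 1.22, above the central range of the random lists (percentile 100, central range -0.06 to 0.05). The glucose transporter genes Slc2a1 and Slc2a3 had log2 ratios of 0.56 ± 0.03 and 0.62 ± 0.22, from signals of 9620 and 48.5 on the control array to 14381 and 75.4. Vegfa, which encodes an angiogenic growth factor, stood at 0.55 ± 0.04, Ndrg1 at 0.50 ± 0.05 and Bnip3, a mitophagy gene, at 0.43 ± 0.05. Among glycolytic enzyme genes Eno2 stood at 0.35 ± 0.04, Tpi1 at 0.30 ± 0.04, Ldha at 0.08 ± 0.05 and Hk1 at 0.02 ± 0.06. The Slc2a1 probe lies on chromosome 5 at 139718779 to 139718838 (rn4).

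Genes of the integrated stress response were also higher on the high dose array, with a median of 0.13 (percentile 100, central range -0.07 to 0.05). Of 23 measured members, 11 were above 0 by more than 2 spot errors and none below 0 by as much. Ddit3, which encodes the stress transcription factor CHOP (probe on chromosome 7 at 67252505 to 67252564, rn4), had a log2 ratio of 0.72 ± 0.05, a fold of 1.65 from a control signal of 17232. Its target Trib3 stood at 0.63 ± 0.06, Cebpb at 0.37 ± 0.06, Ddit4 at 0.30 ± 0.04 and Atf4 at 0.20 ± 0.02. Of the 23 members 7 were below 0, the lowest of them Aldh1l2 at -0.16 ± 0.09 and Atf5 at -0.10 ± 0.06.

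A further 5 lists had medians above the random range at the high dose, by smaller amounts. The p53 targets had a median of 0.13 (percentile 99.9), led by the growth arrest gene Gadd45a at 0.54 ± 0.06 and Tp53inp1 at 0.36 ± 0.08, while the cell cycle inhibitor Cdkn1a stood at -0.05 ± 0.05 and Zmat3 at -0.28 ± 0.07. The immediate early genes had a median of 0.09 (percentile 99.3), with Myc at 0.43 ± 0.03 and Jun at 0.21 ± 0.06 but Egr1 at -0.18 ± 0.12 and Klf2 at -0.34 ± 0.26 (0.61 under the first version of the spot error). The NRF2 targets had a median of 0.08 (percentile 99.6), with the heme oxygenase gene Hmox1 at 0.34 ± 0.03 and Osgin1 at 0.68 ± 0.26 (0.57 under the first version). Genes of cholesterol synthesis had a median of 0.07 (percentile 99.8), with Pmvk at 0.29 ± 0.06 and Lss at 0.26 ± 0.06. The ER chaperones had a median of 0.08 (percentile 99.2), with Hsp90b1 at 0.34 ± 0.06 and Pdia4 at 0.20 ± 0.07. The p53 list lost its place above the random range among genes above the median level, and the ER chaperones lost theirs under 4 of the 11 alternatives.

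DNA replication genes were lower on the high dose array, with a median of -0.20 (percentile 0.00, central range -0.07 to 0.05). With the arrays centred on spike-ins the median was -0.05, at the same percentile. At the main scaling, of 28 measured members, 25 were below 0, 19 of them by more than 2 spot errors, and none was above 0 by as much. Cdt1, which licenses replication origins, had a log2 ratio of -0.54 ± 0.18, and Uhrf1, which maintains DNA methylation behind the fork, stood at -0.44 ± 0.12. Ccne1, encoding cyclin E1, stood at -0.39 ± 0.06, the helicase subunit gene Mcm5 at -0.33 ± 0.07 and the flap endonuclease gene Fen1 at -0.32 ± 0.02. Mitotic genes had a median of -0.07, inside the central range (percentile 3.22), with 20 of 25 members below 0, Plk1 the lowest at -0.42 ± 0.05 and Ttk at -0.19 ± 0.08, and that median turned to 0.08 with the arrays centred on spike-ins.

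Osteoblast genes as a list were lower on the high dose array at the main scaling, with a median of -0.11 (percentile 0.37, central range -0.09 to 0.06), and turned to 0.04 with the arrays centred on spike-in probes, where the percentile was the same. Of 21 measured members 16 were below 0, 7 of them by more than 2 spot errors, and 2 were above 0 by as much, or 1 under the first version of the spot error. Phospho1, a phosphatase gene of matrix vesicles, was the lowest at -0.45 ± 0.13, and the transcription factor gene Msx2 stood at -0.28 ± 0.05. Col1a1, encoding the main bone collagen chain, had a log2 ratio of -0.23 ± 0.05, the osteoblast transcription factor genes Sp7 and Runx2 -0.20 ± 0.11 and -0.16 ± 0.09, and the alkaline phosphatase gene Alpl -0.13 ± 0.06. Ibsp, for bone sialoprotein, stood at -0.02 ± 0.06, and the shift of 0.15 would put Ibsp and Alpl above 0. The osteopontin gene Spp1 was higher, at 0.26 ± 0.02 from 10 spots per array, as was Cdh11 at 0.43 ± 0.15 (0.32 under the first version), and the osteocalcin gene Bglap stood at 0.23 ± 0.24 near the background.

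The 22 measured genes of mineralization and phosphate handling went both ways at the high dose, with a median of -0.01 inside the central range (percentile 47.2) that turned to 0.14 with centring on spike-ins. Galnt3, whose enzyme glycosylates FGF23, had the highest log2 ratio of the list, 0.72 ± 0.11 (signal 263 against 158). Stc1 stood at 0.35 ± 0.07, the pyrophosphate-generating Enpp1 at 0.18 ± 0.03 and the phosphate transporter gene Slc20a1 at 0.16 ± 0.06. The lowest was Smpd3, a sphingomyelinase gene needed for bone mineralization, at -0.57 ± 0.12, followed by Phospho1 and by the phosphate exporter gene Xpr1 at -0.31 ± 0.12.

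**Figure D1:**
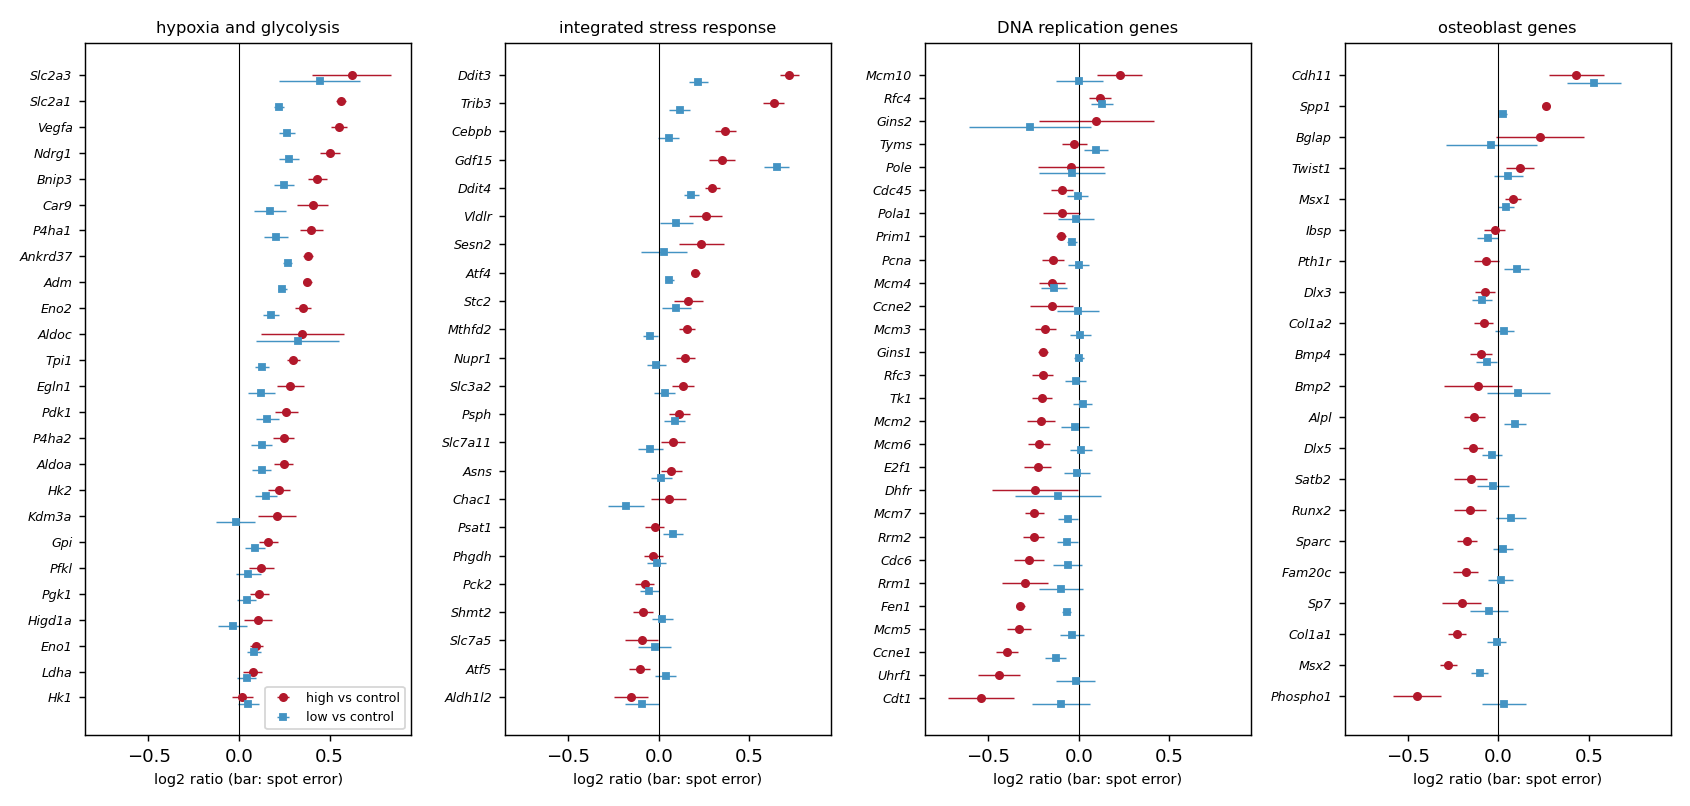
Log2 ratio of each measured member of 4 fixed lists (x axis, log2 units), high dose against control (circles) and low dose against control (squares), with bars of 1 spot error and 1 array per group. All 25 measured of the 29 listed hypoxia and glycolysis genes lay above 0 at the high dose (median 0.28) and 25 of 28 DNA replication genes below it (median -0.20), while the osteoblast median of -0.11 became 0.04 under centring on spike-ins.

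Few genes were 2-fold apart between the high dose and the control: 9 higher and 8 lower of 14503 measured. Of these 17, 15 lay at or below a log2 level of -2.87, the lower quartile of all measured genes, and 7 rested on a single spot per array. The largest with both spots well above background on each array was Ly6d, a GPI-anchored surface protein gene (probe on chromosome 7 at 112872994 to 112873053, rn4), with a log2 ratio of 1.45 ± 0.12, a fold of 2.73. Its spots read 118 and 123 on the control array, 160 and 150 on the low dose array, and 354 and 312 on the high dose array. The lipolysis inhibitor gene G0s2 stood at 1.05 ± 0.22 and Irag1 at 1.10 ± 0.24. Magea13, named Magea11 in the files, had 1 spot per array and stood at 1.16 ± 0.32. Asgr1 stood at 1.43 ± 0.26 as the mean of 2 spots. The spot well above background on both arrays gave 0.99, and the other, not well above background on either, 1.87. Among lower genes, Tmem158 had a log2 ratio of -1.87 ± 0.23, Gng13 -1.22 ± 0.26, Fxyd2 -1.20 ± 0.26 and Gabrd -1.08 ± 0.24, each with 1 of 2 spots well above background at the high dose. That spot alone gave -1.45 for Tmem158, -0.14 for Gng13, -0.48 for Fxyd2 and -1.13 for Gabrd. Under the first version of the spot error the errors were larger, 0.60 for Asgr1, 0.44 for Magea13, 0.39 for Irag1, 0.25 for G0s2, 0.58 for Tmem158, 0.68 for Gng13, 0.60 for Fxyd2 and 0.42 for Gabrd.

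With probes of repeat spots all well above background, a filter added after the data were seen, 3 genes were 2-fold higher (Ly6d, Irag1 and G0s2) and none lower of 8726. Centring on spike-in probes, also added, gave 18 higher and 5 lower, so that 78.3% were higher in place of 52.9%, and normexp gave 1 and 1. Among the 14396 genes measured on all 3 arrays, a smaller set than above, 8 were 2-fold higher and 8 lower at the high dose. Unchanged arrays simulated for these genes from the spot error gave a mean of 1.33 higher and 1.44 lower genes under one version of that error and 36.3 and 37.6 under the other, so whether the count exceeded measurement noise depended on that version. Among bright genes the spread of the ratios exceeded it under both versions: the SD of the log2 ratio over the 7252 genes at or above the median level was 0.13, against a spot error of 0.07.

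Of genes well above background on the high dose or the control array alone, Hdac9 was at least 10.1-fold higher at the high dose and Slco6d1 at least 39.0-fold lower, each from 1 spot per array. The Slco6d1 spot read 433 on the control array, 6.75 at the high dose and 5.14 at the low dose. The next computed bounds were 3.24-fold higher for Rgs11 and 3.23-fold for Apbb1ip, and 3.45-fold lower for Acss3 and 3.06-fold for Ccdc149. Each of these is the observed ratio to the dim probe's own reading. Those of Apbb1ip, Acss3 and Ccdc149 came from 1 spot per array. Another probe of each of these genes was not well above background on either array, so it could neither bear out nor counter the difference. That of Acss3 read 5.94 at the high dose and 5.13 on the control array.

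**Figure D2:**
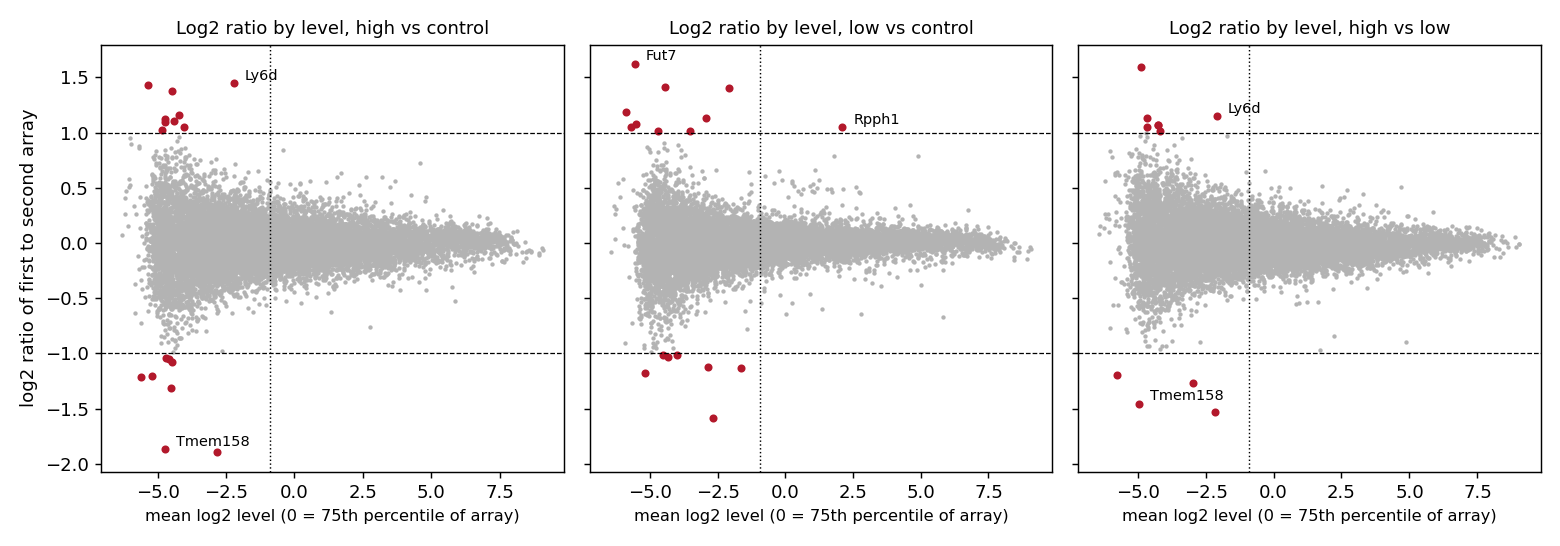
Log2 ratio between 2 arrays (y axis) against the mean log2 level of each gene, with 0 at the 75th percentile of the array (x axis), for the 3 comparisons. Red points are genes at least 2-fold apart (9 higher and 8 lower, 10 and 7, and 7 and 4), dashed lines mark 2-fold and the dotted line the median level; Rpph1 is the 1 red point above that level.

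The second comparison asked the same of the low dose. Hypoxia and glycolysis genes were again higher than on the control array, with a median of 0.14 (percentile 100, central range -0.03 to 0.04), 23 of 26 members above 0 and 14 of them by more than 2 spot errors. Slc2a3 stood at 0.45 ± 0.22, Aldoc, an aldolase gene, at 0.32 ± 0.23, Ndrg1 at 0.27 ± 0.05, Ankrd37 at 0.27 ± 0.03, Vegfa at 0.26 ± 0.04 and Slc2a1 at 0.22 ± 0.03. The growth and differentiation factor gene Gdf15, a member of both the integrated stress response and the p53 lists, had a log2 ratio of 0.65 ± 0.07, with 0.35 ± 0.07 at the high dose. The lists themselves had medians of 0.03 and 0.04, inside the random range.

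The DNA replication list at the low dose had a median of -0.02 (percentile 13.2), turned to 0.14 by centring on spike-ins, and the osteoblast list 0.02 (percentile 81.2), both inside the central range. Alpl stood at 0.09 ± 0.06, Runx2 at 0.07 ± 0.08, Spp1 at 0.02 ± 0.02, Col1a1 at -0.01 ± 0.05, Sp7 at -0.05 ± 0.11, Ibsp at -0.06 ± 0.06 and Bglap at -0.04 ± 0.25. Mitotic genes lay just below the random range with a median of -0.03 (percentile 2.45). This place was lost with random lists not matched on level, quantile normalization, normexp, genes above the median level only and repeat spots only. Centring on spike-ins kept the percentile but turned the median to 0.13. The 5 measured chondrocyte markers had a median of 0.19 (percentile 99.5), lost under normexp, with the transcription factor gene Sox9 at 0.41 ± 0.09 and Hapln1 at 0.23 ± 0.14 (0.25 under the first version of the spot error). Sox6, the 1 of these markers below 0, stood at -0.09 ± 0.09. Galnt3 stood at 0.39 ± 0.12 and Xpr1 at -0.30 ± 0.12 in a mineralization list with a median of 0.03 (percentile 88.8).

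At the low dose 10 genes were 2-fold higher and 7 lower of 14629 measured, 12 of these rested on a single spot per array, and 1, Rpph1, lay above the median level. Rpph1, named Rmrp in the files and typed as an RNase MRP RNA in the RefSeq gene table (probe on chromosome 15 at 26789869 to 26789928, rn4), had a log2 ratio of 1.05 ± 0.08 from 1 spot per array, which read 2784 on the control array, 5994 at the low dose and 3256 at the high dose. The symbol in the gene table differs from the name in the files, and which RNA this probe measures is unresolved. Fut7 stood at 1.62 ± 0.26, the telomerase RNA gene Terc at 1.18 ± 0.26, Tmem253 at 1.13 ± 0.21, Asgr1 at 1.08 ± 0.26, Or52n4d at 1.05 ± 0.26 and Trpm5 at 1.01 ± 0.35. Nsg2 was lower at -1.18 ± 0.26. The ratios of Tmem253 and Trpm5 rested on 1 spot per array. The spots of Fut7 went opposite ways, with log2 ratios of 4.33 and -1.09, and neither was well above background on both arrays. The spot well above background on both arrays gave 0.06 for Terc, 0.50 for Asgr1, 0.17 for Or52n4d and -0.39 for Nsg2. These 2-fold ratios thus came from spots not well above background on at least 1 array. Under the first version of the spot error the errors were 0.61 for Fut7, 0.79 for Terc, 0.68 for Asgr1, 0.74 for Or52n4d, 0.75 for Trpm5 and 0.60 for Nsg2. No gene was 2-fold apart with repeat spots all well above background, and centring on spike-ins gave 16 higher and 2 lower (88.9% higher in place of 58.8%). Among the 14396 genes measured on all 3 arrays, 7 were 2-fold higher and 6 lower at the low dose, and noise simulated for these genes gave means of 1.55 and 1.51 under one version of the spot error and 39.8 and 39.1 under the other. Among the 7315 genes at or above the median level the SD of the log2 ratio was 0.09, against a spot error of 0.07. The largest computed bounds were 3.53-fold higher for Cd226, 2.88-fold for Cplane2 and 2.69-fold for Parvg, and 42.2-fold lower for Slco6d1, 3.02-fold for Adgrb1 and 2.98-fold for Gdf2. Those of Cplane2 and Adgrb1 are observed ratios to the dim probe's own reading. Those of Cplane2, Parvg, Slco6d1 and Gdf2 came from 1 spot per array. Another Parvg probe, not well above background, read 5.43 at the low dose and 5.13 on the control array, too dim to bear out or counter the bound. The bound of Cd226 came from 1 of 2 spots, which read 207 and 5.58 at the low dose against 5.28 and 8.98 on the control array. The repeat spot did not bear it out.

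**Figure D3:**
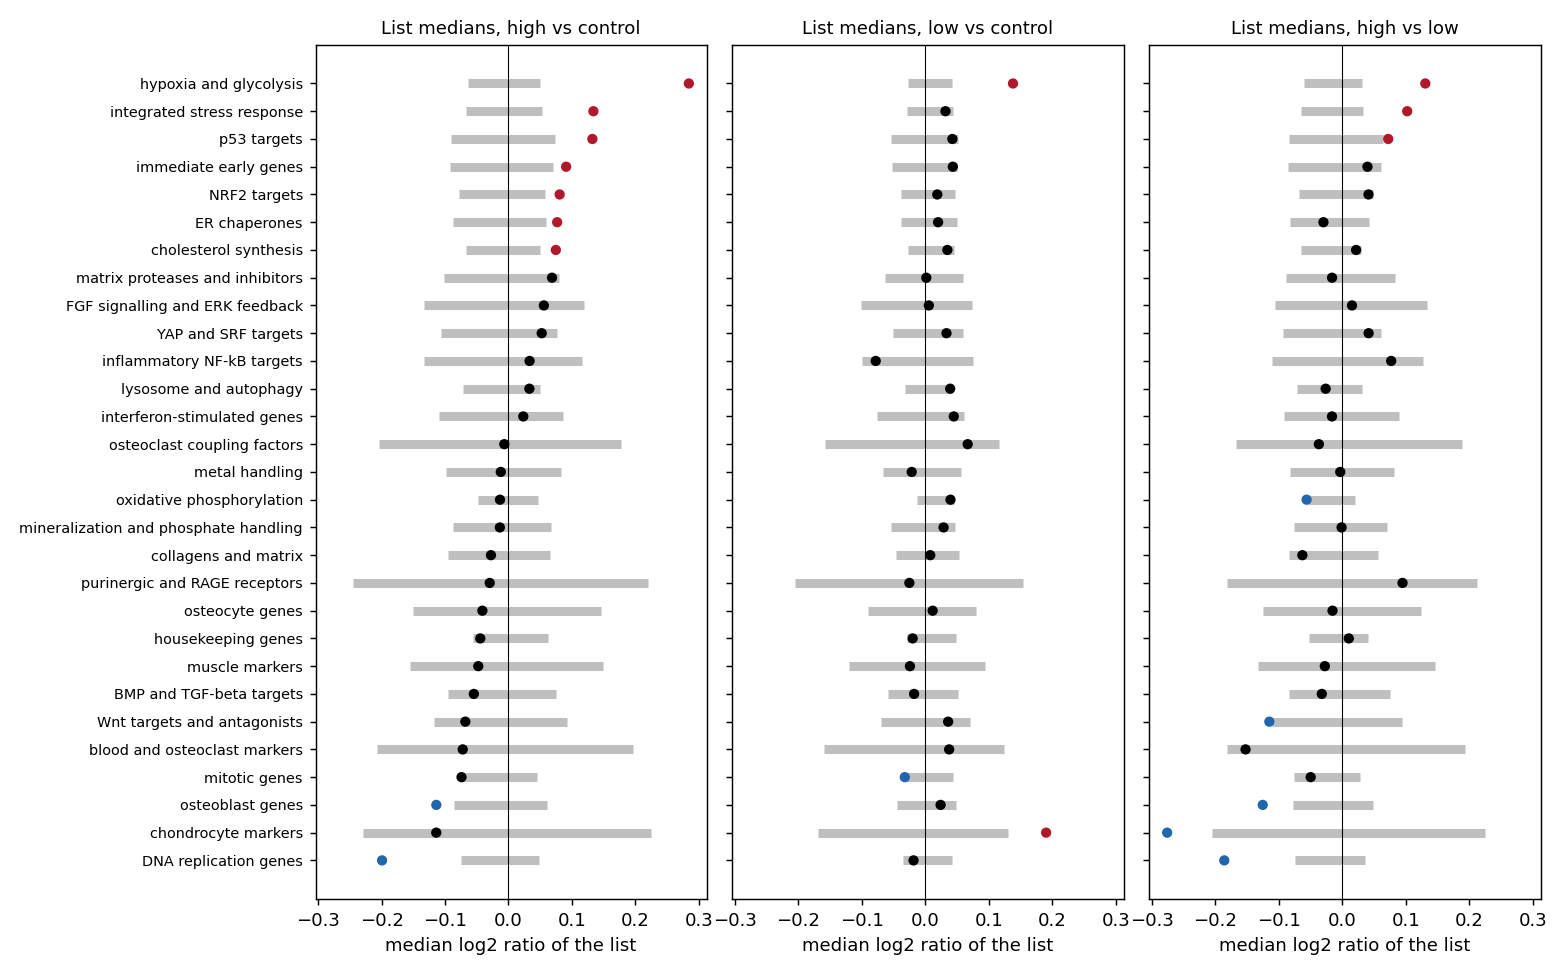
Median log2 ratio of the 29 fixed lists with at least 5 measured members (points) and the central 95% of random lists of the same size and level (grey bars), for the 3 comparisons with 1 array per group. Red points lie above the range (7, 2 and 3 lists) and blue points below it (2, 1 and 5 lists); medians against the control shift up by 0.15 at the high and 0.16 at the low dose under centring on spike-ins, which turns the sign of every negative median against the control except DNA replication at the high dose, the blue osteoblast and mitotic points included.

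The third comparison set the high dose directly against the low dose, without the control array. Hypoxia and glycolysis genes were higher at the high dose, with a median of 0.13 (percentile 100) and 24 of 26 members above 0, as were genes of the integrated stress response, with a median of 0.10 (percentile 100). Slc2a1 stood at 0.34 ± 0.03, Ddit3 at 0.50 ± 0.05 and Trib3 at 0.52 ± 0.06, while the regulator gene Pfkfb3 (-0.77 ± 0.26, near background, with an error of 0.79 under the first version) and Gdf15 (-0.30 ± 0.07) were lower. DNA replication genes were lower at the high dose, with a median of -0.19 (percentile 0.00), 26 of 28 members below 0, Cdt1 at -0.44 ± 0.18 and Uhrf1 at -0.42 ± 0.12. Osteoblast genes were lower with a median of -0.13 (percentile 0.05): Phospho1 stood at -0.48 ± 0.13, Runx2 at -0.23 ± 0.09, Alpl at -0.22 ± 0.06, Col1a1 at -0.22 ± 0.05 and Sp7 at -0.15 ± 0.11, against 0.04 ± 0.06 for Ibsp, 0.24 ± 0.02 for Spp1 and 0.27 ± 0.24 for Bglap. These 4 lists kept their side of the random range under every alternative run. The alternatives that move a whole array by 1 constant could not have changed this.

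A further 4 lists stood outside the random range between the doses, each lost under at least 1 alternative. The p53 targets had a median of 0.07 (percentile 98.4), with Gadd45a at 0.41 ± 0.06, and the median was -0.03 among genes above the median level. The Wnt targets and antagonists had a median of -0.12 (percentile 2.07), with Notum at -0.32 ± 0.14 and Wif1 at -0.23 ± 0.03, and the median was 0.12 without the filter on dim probes. Genes of oxidative phosphorylation had a median of -0.06 (percentile 1.83), with the ATP synthase gene Atp5f1b at -0.21 ± 0.02 but Uqcrc2 at 0.19 ± 0.06. The chondrocyte markers had a median of -0.28 (percentile 0.62), with Hapln1 at -0.57 ± 0.14 (0.34 under the first version of the spot error) and Sox9 at -0.52 ± 0.10. Sox6, the 1 of the 5 measured members above 0, stood at 0.32 ± 0.09. Smpd3 stood at -0.56 ± 0.12 in a mineralization list with a median of -0.00 (percentile 56.6), whose sign was not stable under the alternatives.

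Between the doses 7 genes were 2-fold higher and 4 lower at the high dose of 14488 measured, none above the median level. Ly6d stood at 1.15 ± 0.11, Dapk1 at 1.05 ± 0.25 and Qrfpr, a neuropeptide receptor gene, at 1.01 ± 0.23, against -1.46 ± 0.25 for Tmem158, -1.27 ± 0.22 for Tmem253 and -1.19 ± 0.26 for Bace1. Of these, Ly6d and Qrfpr had repeat spots all well above background on both arrays. Tmem253 rested on 1 spot per array, and its low dose spot, which read 190, also gave its 2-fold ratio for low against control. The spot well above background on both arrays gave -0.21 for Tmem158 and -0.41 for Bace1. Under the first version of the spot error the errors were 0.52 for Dapk1, 0.27 for Qrfpr, 0.58 for Tmem158 and 0.73 for Bace1. The largest computed bounds were 9.11-fold higher for Hdac9, 4.36-fold for Magea13 and 3.68-fold for Apbb1ip, and 3.09-fold lower for Fut7, 2.94-fold for Cd226 and 2.93-fold for Trnp1. Those of Magea13 and Trnp1 are observed ratios to the dim probe's own reading. Those of Hdac9, Magea13, Apbb1ip and Trnp1 came from 1 spot per array. The Hdac9 spot at the high dose, which read 94.3, is the one that gave its bound against the control. Only 1 of 2 spots of Fut7 and of Cd226 was well above background at the low dose. The SD of the log2 ratio above the median level was 0.12, against a spot error of 0.07.

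In all, 9 of the 29 lists tested lay outside the central 95% of random lists for the high dose against control, 3 for the low dose against control and 8 for high against low, where 1.45 would fall outside by chance if genes were independent. At the high dose the medians of the remaining lists were 0.07 for matrix proteases and inhibitors, 0.06 for FGF signalling and ERK feedback, 0.05 for YAP and SRF targets, 0.03 for inflammatory NF-kB targets, 0.03 for lysosome and autophagy, 0.02 for interferon-stimulated genes, -0.01 for osteoclast coupling factors, -0.01 for metal handling, -0.01 for oxidative phosphorylation, -0.03 for collagens and matrix, -0.03 for purinergic and RAGE receptors, -0.04 for osteocyte genes, -0.05 for BMP and TGF-beta targets and -0.07 for Wnt targets and antagonists. All of these lay inside the random range, and so did their medians at the low dose. Centring on spike-ins turned each of the negative ones positive, to 0.09 for Wnt targets and antagonists and 0.14 for oxidative phosphorylation. Among single members Il6, a cytokine gene, had a log2 ratio of 0.54 ± 0.11 from 10 spots per array at the high dose and the metallothionein gene Mt1 0.32 ± 0.07. The dim Lif stood at -0.59 ± 0.26, Ifit2 at 0.60 ± 0.25 and Irf9 at -0.56 ± 0.25, with errors of 0.58, 0.35 and 0.40 under the first version of the spot error, so that all 3 were within 2 errors of 0 there.

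Markers of other cell types had medians inside the random range at the high dose: -0.11 for chondrocyte markers, -0.05 for muscle markers and -0.07 for blood and osteoclast markers, which turned to 0.04, 0.11 and 0.08 under centring on spike-ins. Adipocyte and endothelial markers had 3 measured members each, too few for a median. The 14 measured housekeeping genes had a median of -0.04 at the high dose, -0.02 at the low dose and 0.01 between the doses, all inside the random range, and the first 2 became 0.11 and 0.14 after centring on spike-ins. Ywhaz, among them, stood at 0.25 ± 0.06 at the high dose.

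The log2 ratios of the high and the low dose against the control were compared across the 14396 genes measured on all 3 arrays, which are not independent replicates. Pearson's r was 0.48, and unchanged arrays simulated with the shared control gave 0.50. Above the median level the covariance was 0.00561 against a simulated 0.00243, a difference of 0.00319, so the ratios covaried by more than spot error in the shared control gives. A difference of the control array in labelling or culture, which the spot error leaves out, would raise the covariance too. Pearson's r for these genes was 0.489, against a simulated 0.502. Over all levels the covariance was 0.0151, between the simulated 0.0104 and 0.0183 of the 2 versions of the spot error. Asgr1 and 1 unnamed probe were 2-fold higher at both doses and 1 unnamed probe was lower at both, an overlap that shares the control array. For Asgr1 both calls came from a control spot that was not well above background, so they are not independent.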

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

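Centring on spike-ins, the filter for repeat spots and the version of the spot error used were chosen after the data were seen; the other settings were fixed before. Quantile normalization, centring on the median, the 75th percentile of probes well above background on all arrays, the brightest probe and the series table kept each count of 2-fold genes and each count of lists within 1.5 times. The series table and the centring on the median or on probes well above background rescale whole arrays. They test little else, and their counts of lists could not change. A threshold of 1.5-fold gave 120 higher and 103 lower genes for high against control, 59 and 97 for low against control and 108 and 73 for high against low, and 3-fold gave 0 and 2, 1 and 0, and 1 and 0. Normexp, whose offset shrinks dim ratios, gave 1 and 1, 2 and 1, and 0 and 1. Without the filter on dim probes there were 389 and 449, 260 and 521, and 422 and 251 among 26140 genes, and the correlation of the ratios was 0.551. Genes above the median level alone, fewer in number, left 0 and 0, 1 and 0, and 0 and 0, and 1 list outside the random range at the low dose. Probes with repeat spots left 3 and 0, 0 and 0, and 2 and 0, and 1 such list at the low dose. Centring on spike-ins gave 18 and 5 for high against control and 16 and 2 for low against control, since it moves every ratio against the control up by 0.15 and 0.16; it turned the osteoblast median at the high dose to 0.040 and the mitotic median at the low dose to 0.13, without moving their percentiles. The p53 median between the doses turned to -0.034 among genes above the median level and the Wnt median to 0.12 without the dim filter; the cause was not tested. Hypoxia and glycolysis kept its side of the random range in all 3 comparisons under all 11 alternatives, with medians of 0.25 to 0.44 at the high dose, 0.12 to 0.30 at the low dose and 0.12 to 0.15 between them, and DNA replication at -0.21 to -0.05 for high against control and -0.19 to -0.17 between the doses. Those of the 11 that rescale whole arrays, spike-in centring among them, could not have moved either list from its side. The SD of the spike-in ratios was 0.0436 after quantile normalization for high against control, in place of 0.0245. Signal over background limits the 2-fold genes, most of which are dim. Leaving out replicates was not possible. No paired analysis was possible because each group has 1 array.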

Other observations

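The tests that set the high dose directly against the low dose were chosen only after the result was seen; those on GC content, on the place of the spots and on transcripts without a poly(A) tail were written down before their results were seen.

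Some genes outside the rule for named genes, chosen after their values were seen, also differed between the high dose and the control by more than 2 spot errors. The hypoxia-inducible oxidoreductase gene Ero1a had a log2 ratio of 0.60 ± 0.06 at the high dose, the clock and hypoxia gene Bhlhe40 0.55 ± 0.08, the MYC antagonist gene Mxi1 0.43 ± 0.05 and the eIF2 alpha phosphatase subunit gene Ppp1r15a 0.60 ± 0.06. The ER stress transducer gene Creb3l1, which acts on collagen secretion in osteoblasts, stood at -0.38 ± 0.05 and the cell cycle transcription factor gene Mybl2 at -0.38 ± 0.05. Gdf15 did not follow the dose: its signal was 626 on the control array, 1023 at the low dose and 807 at the high dose.

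Hypoxia and glycolysis genes were higher on the high dose array (median log2 ratio 0.28). A low reading of the control array alone is argued against by the direct comparison of the doses, where the median was 0.13, above the random range. Removing a trend with the GC content of the probes left a median of 0.30, and removing a trend over 12 by 8 blocks of the array left 0.31. Both trends were small, with medians from -0.09 to 0.03 over GC bins and from -0.06 to 0.05 over blocks. Neither was large enough to account for 0.28, so removing them could hardly have changed the outcome. A response to polyphosphate that grows with the dose would also give the 0.14 at the low dose. That value shares the control array with the 0.28, so a low reading of that array could give the 0.14 and part of the 0.28. A difference between cultures in cell density, oxygen or time to harvest may do the same. With 1 array per dose all of these stay open, and no test here separates them.

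DNA replication genes were lower on the high dose array (median log2 ratio -0.20). The median was -0.19 against the low dose array, below the random range, which argues against a high reading of the control array alone. It was -0.18 after the GC trend was removed and -0.19 after the trend over the array was removed, both below the random range. With lowest medians of -0.09 over GC bins and -0.06 over blocks, these trends were too small to give -0.20. Fewer cells in S phase at the high dose is a candidate explanation that was not tested, and so is a denser or older culture.

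Rpph1 and, on weaker evidence, Terc, whose RNAs are not ordinary poly(A) mRNAs, had 2-fold higher values on the low dose array. More labelling of such transcripts on that array would lift others too, but the median of 24 other genes of this kind, all of them replication-dependent histone genes, was -0.088 there, below the random range (percentile 0.00). That argues against a general cause of this kind, although histone mRNA also follows the cell cycle. The RNA called Rpph1 here is named Rmrp in the files, and which of these it is remains unresolved. It was read by 1 spot per array, and the Terc spot well above background on both arrays gave a log2 ratio of 0.06, the rest of its difference coming from a spot that was not, so a fault of single spots stays open as a possible explanation and was not tested.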
